A study of Mus musculus with 6 samples.

How the data were processed

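Gene expression was measured in erythroblasts sorted from the bone marrow of 6 mice, 3 lacking the miR-144/451 locus (knockout, KO) and 3 wild type (WT). Per the labels, cells positive for both Ter119 and CD71 with high forward scatter were sorted straight into Trizol LS. Ter119 marks the erythroid lineage, CD71 is the transferrin receptor, and high forward scatter selects large cells. Total RNA was labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays, with 1 array per mouse. Groups came from the sample titles, which carry the numbers 497, 504 and 550 for WT and 493, 548 and 551 for KO. These were read as mouse numbers, which the labels do not state; the same numbers stand in a label for a microRNA construct, whose meaning there is unclear. No number occurs in both groups, and no mice were treated as pairs. Strain, age and litter were not used here.

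The deposited values were probe-set intensities made by the authors with RMA (robust multi-array average), per the submitters' processing notes, which name no software or version. RMA fits the probes of all arrays together and forces the arrays toward a shared distribution, so a shift of most transcripts in 1 genotype would be partly removed before deposit. The background step was not given in the sources used here, and detection calls were not used. The deposited intensity values were linear with a lowest value of 1, and 100% of them equalled a power of 2 with a 2-decimal exponent. They were therefore returned to the log2 scale before testing, with no further normalization or pseudocount. Array medians on that scale were 5.78, 5.73 and 5.77 in WT 497, 504 and 550, and 5.65, 5.62 and 5.68 in KO 493, 548 and 551. The median log2 fold change of all probe sets was -0.04.

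The table held 45101 probe sets, of which 64 controls were left out and 45037 were tested. Gene names came from GEO's annotation of the platform: 34958 probe sets had 1 gene, 932 had several and 10092 tested probe sets had no name here. Gene identifiers were matched to NCBI RefSeq genes of mouse assembly GRCm38.p6, with a match for 99.4% of genes; that table gave only current symbols, chromosomes and the order of genes. A probe set with several genes named none. Each of 18193 genes was represented by its probe set with the highest mean log2 intensity over the 6 arrays. Such a probe set can miss the transcript form that changed, and genes of a family can share probes.

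Differences are log2 KO minus WT. They were tested per probe set with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05 on the adjusted p. A gene was called by its representative probe set. Standard errors are limma's moderated ones, and SDs are over 3 mice. The number of arrays limits precision, and the moderated standard errors also draw on a variance shared over all probe sets. For genes with a small spread this makes the standard error larger, as for Cab39 (SE 0.09, SDs 0.05 in KO and 0.02 in WT).

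The design, the alternatives, 30 gene lists and the rule for naming genes were fixed before the data were examined. The lists covered candidate targets of miR-451 and miR-144, 14-3-3 proteins, the CAB39-LKB1-AMPK pathway, FOXO targets, antioxidant enzymes, NRF2 targets, globins with AHSP, haem synthesis, iron handling, erythroid transcription factors, red cell membrane and surface genes, early progenitor and late erythroblast genes, DNA replication, mitosis, autophagy, p53 targets, the integrated stress and unfolded protein response, heat shock proteins, immediate early genes, the interferon response, ribosome biogenesis, 6 sets of markers of other blood cells, and neighbours of the locus. They named 512 distinct genes, of which 469 were measured under those symbols; the others were not analysed here. The lists were written from general knowledge, so candidate targets include genes that studies of these mutants may have established. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 30 lists, and again with a correlation estimated from the residuals. List scores, the mean log2 intensity over members, were compared by exact two-sided permutation tests, in which 3 mice against 3 cannot give a p below 0.1. List medians were also set against 10000 random lists of the same size matched on mean level in 50 bins.

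Named genes are the 12 called genes with the largest rise and the 12 with the largest fall whose groups did not overlap. To these were added, per list, up to 4 called members with the largest change or otherwise the 2 members with the smallest p, and a fixed set (Ywhaz, Cab39, Foxo3, Cat, Gpx1, Gata1, Klf1, Alas2, Hba-a1, Slc4a1, Kit, Eral1 and Flot2). Hbb-b1 was also planned for the fixed set but was not measured under that symbol. Called genes among the 50 measured genes on each side of the locus were compared with the other genes by two-sided Fisher's exact test, with 20 and 200 genes per side as alternatives. Chromosomes were compared in the same way.

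The procedure was tested on simulated data with the real means and variances of the 45037 probe sets and 3 arrays per group. It called 0 of 67 probe sets changed by 0.5 on the log2 scale, 26.9% of those changed by 1 and 86.4% of those changed by 2, with 0 false calls. Alternatives were a filter on dim probe sets, quantile or cyclic loess normalization of the deposited values, an intensity trend with a robust prior, array weights, a block for low against high mouse numbers, averaging or filtering probe sets, other thresholds, an ordinary equal-variance test, and leaving out each mouse. A test of microRNA seed sites had been planned but was not run, because it needs transcript sequence, which was not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.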

Results

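The study compared sorted bone marrow erythroblasts of 3 mice lacking the miR-144/451 locus with those of 3 wild-type mice. The locus encodes microRNAs that are abundant in maturing red cells, and the comparison asks which transcripts differ when they are missing. The microRNAs themselves were not analysed here, so genotypes rest on the labels. Each mouse gave 1 array of 45101 probe sets. Mean correlations with arrays of the same genotype were 0.986 to 0.990, and with the other genotype 0.980 to 0.985. The first principal component, with 38.3% of the variance, separated the genotypes: KO arrays scored 24.9 to 45.9 and WT arrays -60.2 to -22.3, with WT 497 farthest out. The second, with 21.9%, cut across genotype: WT 497 scored 30.3 and KO 493 46.2, and the other arrays -30.9 to -4.0.

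Erythroblasts without miR-144/451 differed from wild type in 70 called genes, 43 higher and 27 lower, and 45 of these changed at least 2-fold. Called changes ran from 5.30 ± 0.22 (log2, SE, n = 3 per group) for Elobl to -3.88 ± 0.14 for the C-type lectin Clec2g, each against a group with signals near the bottom of the scale. Among genes central to red cell identity, Gata1, the master erythroid transcription factor, was at 0.01 ± 0.10 and Slc4a1, the band 3 anion exchanger, at -0.07 ± 0.09. Over all probe sets, 160 were called, 83 higher and 77 lower, and 8927 had an unadjusted p under 0.05. In all 70 called genes the 3 KO values lay on one side of the 3 WT values, which largely follows from the call itself. Such separation held for 28.8% of all genes, where chance gives 10%. Another quantile normalization of the deposited values called 69 genes higher and 24 lower. The count rests on every mouse: it was 13 without WT 497, 13 without WT 504, 9 without WT 550, 14 without KO 493, 5 without KO 548 and 13 without KO 551. Over the planned limma fits of all arrays at the same threshold it ranged from 10, with a block for low against high mouse numbers, to 804, with an intensity trend and robust prior.

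Among the 12 largest rises, 6 genes lay on chromosome 11, which carries the deleted locus: Elobl, Dnah2, Irgm2, Myo15, Nle1 and Drg2. Elobl went from a mean log2 intensity of 3.63 ± 0.45 in WT to 8.92 ± 0.07 in KO (SD, n = 3; adjusted p = 0.00167). Dnah2, an axonemal dynein heavy chain, rose by 4.71 ± 0.31 (SE, adjusted p = 0.00726). Its other probe set was not called higher, and the mean of both rose by 2.46 (adjusted p = 0.011), so they disagree on the size. Irgm2, an interferon-inducible GTPase, rose by 2.95 ± 0.16 (adjusted p = 0.0042) and Myo15, an unconventional myosin of the inner ear's hair cells, by 2.94 ± 0.27 (adjusted p = 0.0178). Nle1, a ribosome assembly factor, rose by 2.08 and Drg2, a GTP-binding protein, by 1.43. The others were Cda, cytidine deaminase (2.31 ± 0.15), Cbx3, which encodes heterochromatin protein 1 gamma (1.99 ± 0.13), Bex4 (1.74 ± 0.11), Asap2, a GTPase-activating protein for ARF (1.58 ± 0.13), Art3, an ADP-ribosyltransferase family member (1.5 ± 0.13), and Degs2, a sphingolipid desaturase (1.49 ± 0.12). The WT means of Elobl, Cda (3.47), Degs2 (4.13) and Dnah2 (4.30) lay under the 25th percentile of the WT arrays, 4.35 to 4.40, so the sizes of these rises are set by signals near the bottom of the scale. Bex4 was the brightest of the 12 in KO, at 11.87 ± 0.02 against 10.12 ± 0.14 in WT (SD). Averaging a gene's probe sets ended the call of Art3 (0.66, adjusted p = 0.122).

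Of the 12 largest falls, 7 lay on chromosome 11: Xaf1, Ccdc92b, Slc22a21, Slc2a4, Tnfsf13os, Wfdc17 and Pctp. Slc2a4, which encodes the insulin-responsive glucose transporter GLUT4, changed by -1.88 ± 0.13 (adjusted p = 0.00842), and its other probe set was also called lower. Changes were -2.27 ± 0.18 for Ccdc92b, -2.19 ± 0.23 for the carnitine transporter Slc22a21, -1.85 ± 0.19 for Tnfsf13os, -1.61 ± 0.22 for Wfdc17 (adjusted p = 0.04998) and -1.47 ± 0.11 for Pctp, the phosphatidylcholine transfer protein. The probe sets of Xaf1, an interferon-inducible regulator of apoptosis, went opposite ways: the brighter was at -3.26 ± 0.18 (adjusted p = 0.00423) and the other at 4.23 (adjusted p = 0.0142), so the array gives no single direction for this gene. Off chromosome 11 lay Clec2g, Artn, the neurotrophic factor artemin (-1.66 ± 0.17), Rsph9, a radial spoke protein of cilia (-1.65 ± 0.17), 9630013D21Rik (-1.60 ± 0.18) and 2500002B13Rik (-1.56 ± 0.14). Clec2g fell from 5.10 ± 0.14 to 1.22 ± 0.20 (SD), under the 25th percentile of the KO arrays, 4.30 to 4.34, so its fold is set by signals near the bottom of the scale, as is that of Tnfsf13os, with a KO mean of 3.86. With probe sets averaged, Tnfsf13os (-0.96, adjusted p = 0.0937) and Pctp (-0.73, adjusted p = 0.062) were no longer called.

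The calls of single genes depended on the number of mice. Among the 26 called genes that the naming rule picked, 4 stayed called whichever mouse was left out: Elobl, Irgm2, Clec2g and Xaf1. For 4 more, Dnah2, Cda, Cbx3 and Bex4, the call ended only without KO 548. A further 8 were called in some of the 6 reduced fits and 10 in none, among them Drg2, Slc22a21, Gabarapl1 and Eral1.

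Called genes were concentrated on chromosome 11, where 23 of 1452 measured genes (1.58%) were called, 12 higher and 11 lower, against 47 of 16741 genes elsewhere (0.281%). The odds ratio was 5.72 (95% interval 3.3 to 9.64, two-sided Fisher's exact test, adjusted p over chromosomes 4.54e-08). With fewer calls in all, chromosome 11 held 6 of 13 called genes without WT 497, 7 of 13 without WT 504, 5 of 9 without WT 550, 6 of 14 without KO 493, 4 of 5 without KO 548 and 5 of 13 without KO 551. With more calls in all its share shrank from 32.9% to 15.3% under the level filter (72 of 472 genes) and 13.1% with the intensity trend (105 of 804). In the planned window of 50 genes on each side of the locus, 2 of 100 genes were called, which missed the threshold (odds ratio 5.41, 0.633 to 20.8, Fisher's exact p = 0.0568). These were Eral1, a mitochondrial ribosome assembly GTPase and the next measured gene on one side (-0.75 ± 0.10, adjusted p = 0.04998), and Vps53, a subunit of the Golgi tethering complex GARP (1.01, adjusted p = 0.0437), which is named because the count is small, after its value was seen. Eral1 lost its call under renewed quantile (adjusted p = 0.0563) and cyclic loess normalization (adjusted p = 0.0503), and with the block (adjusted p = 0.113). It also lost it as the mean of its probe sets (-0.40, adjusted p = 0.134), of which 1 was at 1.02 and the others at -0.75 to -0.51. Neither gene was called in any fit without 1 mouse. The wider window of 200 genes per side held 15 called genes of 400 (odds ratio 12.6, 6.53 to 22.8, Fisher's exact p = 2.51e-11). Its count was 5, 6 and 4 without WT 497, 504 or 550, 5, 2 and 4 without KO 493, 548 or 551, 4 with the block, 38 with the level filter and 44 with the trend. In the list of the locus's neighbours, 1 of 17 measured members, Eral1, was called lower, 0 and 2 were called higher and lower adjusted over the list alone, and the list as a set was not called (adjusted p = 0.305); Flot2, a raft scaffold protein and the next measured gene on the other side, was at -0.41 ± 0.21 (adjusted p = 0.325).

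**Figure D1:**
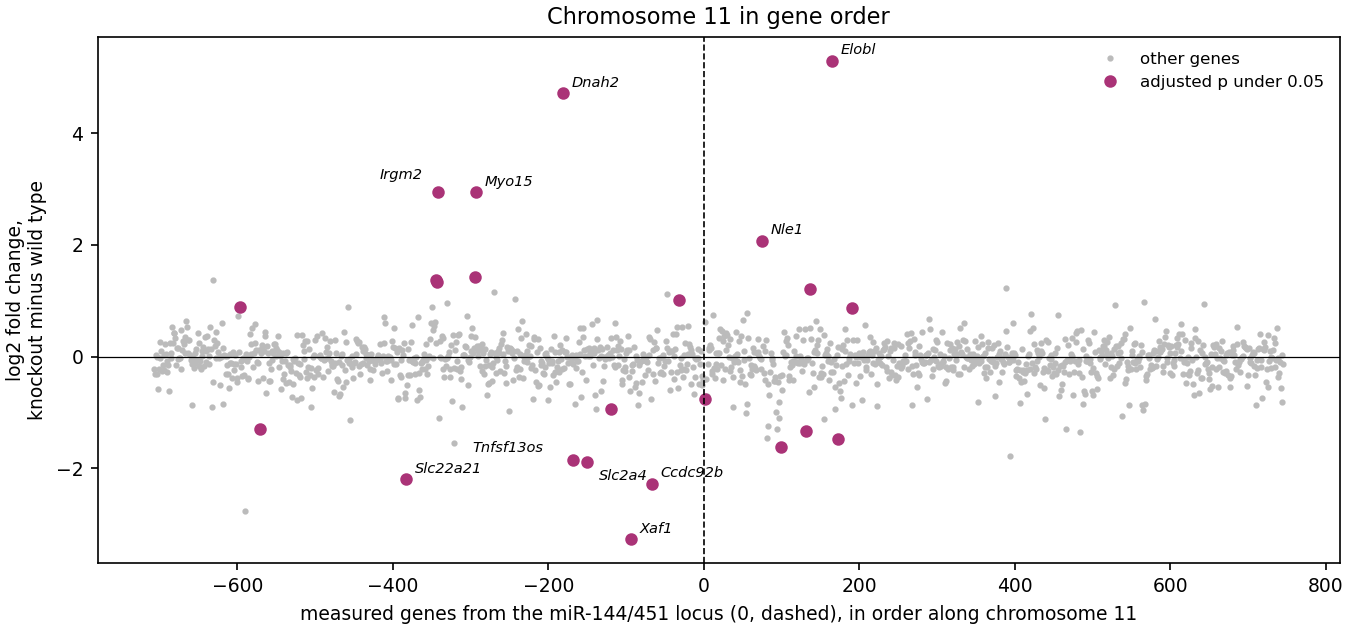
Log2 fold change (knockout minus wild type, n = 3 mice each) of the 1452 measured genes of chromosome 11, against their position in measured genes from the miR-144/451 locus at 0; purple points are the 23 called genes. The called genes lie from position -597 to position 190, and include Elobl at 5.30 and Xaf1 at -3.26, whose other probe set was at 4.23.

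Candidate direct targets were not called over all genes. Of 22 measured candidate miR-451 targets, limma called 0 over all genes, 10 had an unadjusted p under 0.05, and 4 higher and 3 lower passed adjusted over the list alone. The fit with an intensity trend and robust prior called 6 of them, 4 higher, the level filter 2 and an ordinary equal-variance test 0. Cab39, a scaffold that activates the kinase LKB1, was at 11.35 ± 0.05 in KO and 10.88 ± 0.02 in WT (SD, n = 3), a difference of 0.47 ± 0.09 (SE, adjusted p = 0.0892). Ywhaz, the 14-3-3 zeta adaptor that can hold FOXO proteins in the cytoplasm, was at 12.25 ± 0.09 and 11.84 ± 0.06, a difference of 0.41 ± 0.10 (adjusted p = 0.123). Each was higher in 3 of 3 KO mice than in any WT mouse. The intensity trend fit called Cab39 (adjusted p = 0.00507) and Ywhaz (adjusted p = 0.00817), and the filter on dim probe sets called Cab39 (adjusted p = 0.0318). Bcl2, the antiapoptotic protein, was at -1.03 ± 0.17 (adjusted p = 0.0678), and was called with the trend (0.0188) and the level filter (0.0321). Since candidate targets may have been established in these mutants, the list is not independent evidence of direction. Its median was 0.01, its mean -0.05, and camera, which ranked it upward, did not call it (adjusted p = 0.305).

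None of 13 measured candidate miR-144 targets was called by limma, over all genes or adjusted over the list alone; 5 had an unadjusted p under 0.05, the trend fit called 2, both higher, and an ordinary test 0. The set was not called (adjusted p = 0.719, camera direction up, median -0.03, mean -0.04). Nfe2l2, which encodes the antioxidant regulator NRF2, was at 0.42 ± 0.11 (adjusted p = 0.127) and Abca1, a cholesterol exporter, at -0.56 ± 0.15 (adjusted p = 0.14). With the intensity trend Nfe2l2 was called (adjusted p = 0.0388). Among 7 14-3-3 genes 1, Ywhaz, passed adjusted over the list alone. The set had a median of 0.08 (adjusted p = 0.364), and Ywhah was at -0.21 ± 0.10. By limma 0 of the 7 were called and 1 had an unadjusted p under 0.05, while the trend fit called 2, Ywhaz and Ywhah. The CAB39-LKB1-AMPK list had 0 of 12 members called by limma and 3 with an unadjusted p under 0.05, while the trend fit called 2 and the level filter 1, Cab39 in both. It had 1 higher and 1 lower adjusted over the list alone, and a median of -0.06 (adjusted p = 0.785); Prkag2, a regulatory subunit of AMPK, was at -0.77 ± 0.20 (adjusted p = 0.131).

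**Figure D2:**
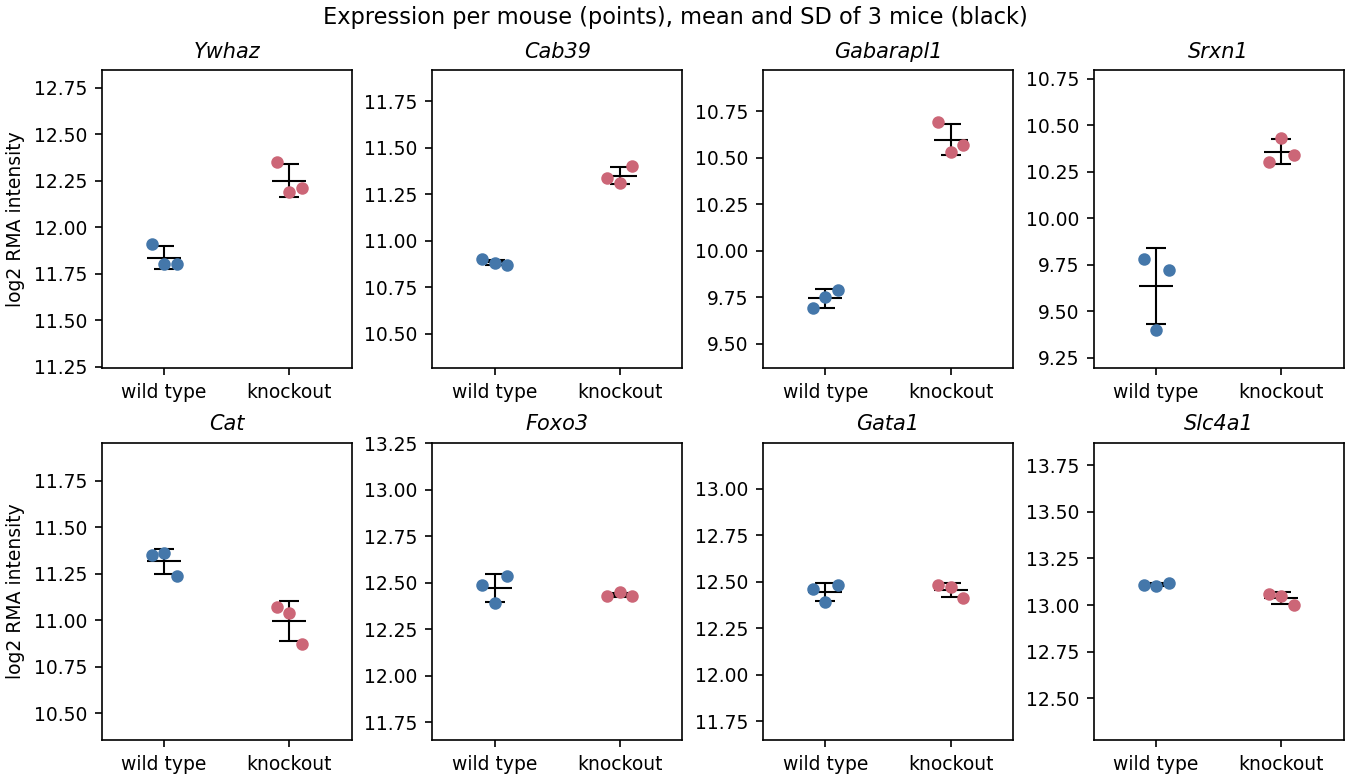
Log2 RMA intensity of 8 genes in each wild-type and knockout mouse (points), with the mean and SD of 3 mice in black; every panel spans the same log2 range around its own mean. Knockout mice lie above wild-type mice for Ywhaz (12.25 against 11.84), Cab39, Gabarapl1 and Srxn1, of which only Gabarapl1 was called, while Gata1 and Foxo3 overlap.

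The core erythroid programme held 0 genes called by limma over all genes. Unadjusted p lay under 0.05 for 3 of 17 transcription factors, 0 of 14 haem synthesis genes, 3 of 15 iron genes and 3 of 6 globin genes, and the trend fit called 2, 0, 2 and 1 of them, the level filter 2, 0, 0 and 1. The 17 erythroid transcription factors had a median of -0.04, a mean of 0.06 and an adjusted p of 0.732, with 1 higher and 1 lower adjusted over the list alone: Mllt3, a chromatin reader, at 0.55 ± 0.12 (adjusted p = 0.0971) and the repressor Klf3 at -0.40 ± 0.09 (adjusted p = 0.111). Mllt3 was called as the mean of its probe sets (0.81, adjusted p = 0.0415) and without probe sets ending in _x_at or _s_at (1.07, adjusted p = 0.028). Klf1, the activator of adult globin genes, was at -0.10 ± 0.11. Haem synthesis genes (14 measured, 0 called, 0 adjusted over the list alone, median -0.04, adjusted p = 0.963, camera direction up) included Alas2, the first enzyme of the pathway in red cells, at -0.13 ± 0.10, Slc25a38 at -0.23 ± 0.12 and Cpox at -0.18 ± 0.10. For iron handling (15 measured, 0 called, 0 adjusted over the list alone) the median was -0.07 (adjusted p = 0.64); Tfr2, transferrin receptor 2, was at 0.44 ± 0.12 (adjusted p = 0.135) and Hfe at -0.81 ± 0.21 (adjusted p = 0.132). The globin list had 6 measured members and was not called (median -0.46, adjusted p = 0.191). The beta-globin gene Hbb-b1 was not measured under that symbol and has no value here. Adjusted over the list alone 1 member was lower, the embryonic globin Hbb-y (-1.28 ± 0.24, adjusted p = 0.0834). The globin set was called with the trend (adjusted p = 0.0404), and without it had an adjusted p = 0.607 with an estimated correlation. Embryonic Hbb-bh1 was at -0.92 ± 0.35, and the probe set of Hba-a1 was too dim to read, at 2.18 ± 0.94 in KO and 2.96 ± 0.23 in WT (SD).

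Several erythroid and cell cycle groups lay slightly lower in KO as sets, on arrays where markers of other blood cells were lower too (mean list difference -0.488) and the actin 3' minus 5' signal was 1.65 to 1.67 in WT and 1.82 to 1.86 in KO. Early progenitor genes had a median of -0.41, with 15 of 16 members lower (adjusted p = 0.00252 preset, adjusted p = 0.607 with an estimated correlation), 0 called by limma, 10 with an unadjusted p under 0.05 and 3 lower adjusted over the list alone. The trend fit called 4 and the level filter 2, Erg and Cd34 in both. The list includes Cd34, a progenitor surface protein, at -0.83 ± 0.17, the transcription factor Erg at -0.65 ± 0.12 and the growth factor receptor Kit at -0.51 ± 0.26 (adjusted p = 0.0955, 0.0792 and 0.334). Late erythroblast genes had a median of -0.13, with 21 of 23 lower (adjusted p = 0.00483), and red cell membrane genes a median of -0.13, with 19 of 22 lower (adjusted p = 0.0329). Both calls were lost with an estimated correlation (adjusted p = 0.607 for each), and the late erythroblast median was -0.197 with a gene's probe sets averaged. Limma called 0 genes of either list, with 6 late and 4 membrane genes at an unadjusted p under 0.05, while the trend fit called 5 and 2, and the level filter 1 and 0. Adjusted over the list alone 1 late gene, Ube2l6, an ISG15-conjugating enzyme, was lower (-0.69 ± 0.11, adjusted p = 0.0625) and 0 membrane genes. Bcl2l1, an antiapoptotic gene of late erythroblasts, was at -0.33 ± 0.11, Icam4 at -0.38 ± 0.11 and the cytoskeletal protein Dmtn at -0.37 ± 0.11. Mitosis genes had a median of -0.13, with 20 of 25 lower (adjusted p = 0.00562 preset, adjusted p = 0.607 with an estimated correlation), 0 called by limma, 6 with an unadjusted p under 0.05 and 3 lower adjusted over the list alone, among them the kinase Aurkb (-0.78 ± 0.13, adjusted p = 0.0672) and the centromere protein Cenpf (-0.58 ± 0.09, adjusted p = 0.0663). The trend fit called 5 and the level filter 3, these 2 genes in both. As the mean of its 2 probe sets, which differ in size, Aurkb was called at -1.74 (adjusted p = 0.011). Aurkb lies on chromosome 11, at position -200 in measured genes from the locus, within the span of the called genes there. DNA replication genes were not called as a set (25 measured, median -0.07, adjusted p = 0.226), but passed under cyclic loess (adjusted p = 0.044) and the trend (adjusted p = 0.0233). In the fit without these changes this set had an adjusted p = 0.607 with an estimated correlation. Limma called 0 members, 0 adjusted over the list alone, with 2 at an unadjusted p under 0.05, the trend fit 2 and the level filter 1. E2f1 was at -0.54 ± 0.11 and Ccne2 at -0.28 ± 0.11. The red cell membrane call also ended without WT 497 (adjusted p = 0.113), WT 550 (0.0763) or KO 551 (0.101), and with the block (0.0696).

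FOXO targets, which include antioxidant and autophagy genes and lay lower alongside markers of other blood cells and a higher actin 3' minus 5' signal (1.82 to 1.86 in KO, 1.65 to 1.67 in WT), had a median of -0.13, with 22 of 29 lower (adjusted p = 0.0412 preset, adjusted p = 0.607 with an estimated correlation). Of its members 10 had an unadjusted p under 0.05, and the trend fit called 4, of which 1 was higher. The 1 member called by limma was Gabarapl1, an ATG8-family autophagy gene, which rose by 0.85 ± 0.10 (adjusted p = 0.0342). Its other probe set was also called. With the block for low against high mouse numbers Gabarapl1 was not called (adjusted p = 0.0946). Adjusted over the list alone it was also the 1 gene to pass. Foxo3, the main FOXO factor of erythroblasts, was at -0.04 ± 0.10, the peroxide-removing enzyme Cat (catalase) at -0.32 ± 0.11 (adjusted p = 0.181, or 0.0455 and called with the intensity trend) and the glutathione peroxidase Gpx1 at -0.05 ± 0.09. The set lost its call without WT 497 (adjusted p = 0.064), WT 550 (0.0674), KO 548 (0.19) or KO 551 (0.0775), and also with the block (0.0808), the level filter (0.0684) or the mean of probe sets (0.0548). Its median was -0.20 without WT 504 and -0.20 without KO 493. Antioxidant enzymes (22 measured, median -0.04, mean 0.03, adjusted p = 0.719, camera direction up) and NRF2 targets (18 measured, median -0.06, adjusted p = 0.719) held 0 genes called by limma, with 3 and 4 at an unadjusted p under 0.05. The trend fit called 2 and 3 and the level filter 1 and 2, with Srxn1 and Gstm1 in both. Adjusted over the list alone 1 gene was higher in each, Srxn1, which repairs oxidised peroxiredoxins (0.72 ± 0.13, adjusted p = 0.0771), and 1 NRF2 target was lower, Gstm1, a glutathione transferase (-0.79 ± 0.14, adjusted p = 0.0744). Gss, glutathione synthetase, was at 0.60 ± 0.16. The autophagy list (19 measured) had 1 called member, Gabarapl1, and 2 higher adjusted over the list alone, the other being Atg5, which takes part in lipidation of ATG8 proteins (0.68, adjusted p = 0.0569). Its median was -0.04, its mean 0.03 and its adjusted p 0.719, camera direction up.

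Stress and growth lists moved in both directions, on the same arrays with lower markers of other blood cells and a higher actin 3' minus 5' signal in KO (1.82 to 1.86, against 1.65 to 1.67 in WT). Immediate early genes, which respond within minutes to handling and signals, had a median of -0.49, with 16 of 16 lower (adjusted p = 0.00149 preset, adjusted p = 0.607 with an estimated correlation), 0 called by limma (7 at an unadjusted p under 0.05, 1 called by the trend fit) and 0 adjusted over the list alone. Klf4 was at -1.03 ± 0.27 and the mRNA-decay factor Zfp36 at -0.69 ± 0.18. The integrated stress and unfolded protein response list had a median of -0.24, with 20 of 22 lower (adjusted p = 0.0145 preset, adjusted p = 0.607 with an estimated correlation), 0 called by limma (7 at an unadjusted p under 0.05, 0 called by the trend fit) and 0 adjusted over the list alone. Cebpb was at -0.55 ± 0.16 and Dnajb9 at -0.36 ± 0.11. The call of this set ended without KO 493 (adjusted p = 0.0666) and with the level filter (adjusted p = 0.059). Ribosome biogenesis was the 1 set called higher, with a median of 0.17 and 17 of 20 members higher (adjusted p = 0.00483 preset, adjusted p = 0.607 with an estimated correlation), 0 called by limma (3 at an unadjusted p under 0.05, 0 called by the trend fit) and 0 adjusted over the list alone. Nip7 was at 0.39 ± 0.14 and Nop2 at 0.33 ± 0.12. The set was not called without WT 497 (median 0.08, adjusted p = 0.106) or KO 548 (median 0.09, adjusted p = 0.062), and its median was 0.11 with the block. Its list scores overlapped between the groups, at 9.242 to 9.542 in WT and 9.447 to 9.693 in KO (exact permutation p = 0.3). Interferon response genes were not called (17 measured, median -0.27, adjusted p = 0.0567). Their 1 called member, also the 1 gene to pass adjusted over the list alone, was Xaf1, with its opposed probe sets. The set passed with all mice under quantile (adjusted p = 0.0391) or cyclic loess normalization (0.0362) and with the trend (0.0323), and also without WT 550 (0.0148) or KO 551 (0.0082). In the fit of the deposited values its adjusted p was 0.607 with an estimated correlation. The p53 targets (19 measured, median -0.23, adjusted p = 0.226) and heat shock proteins (12 measured, median 0.01, adjusted p = 0.711) held 0 genes called by limma, 0 adjusted over the list alone, with 4 and 1 at an unadjusted p under 0.05. The trend fit called 1 of each, Ccng1 and Hspa4l, and the level filter 0. Bbc3 was at -0.87 ± 0.22, Ccng1 at 0.43 ± 0.12, Hspa4l at -0.44 ± 0.12 and Hspd1 at 0.33 ± 0.18.

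Markers of other blood cells lay lower in KO in 5 of 6 lists, alongside the sets above. Medians were -0.34 for neutrophil (14 of 14 lower), -0.34 for macrophage and monocyte (14 of 15), -0.54 for B cell (12 of 13), -0.62 for T and NK cell (11 of 12) and -0.63 for eosinophil, basophil and mast cell markers (9 of 9). Adjusted p were 0.00252, 0.00562, 0.00421, 0.0412 and 0.00252, and adjusted p = 0.607 for each with an estimated correlation. None of their members was called by limma, although 5, 6, 8, 2 and 6 had an unadjusted p under 0.05 in the order given and the trend fit called 0, 1, 0, 0 and 1. Adjusted over the list alone 5 passed, all lower and all in the eosinophil, basophil and mast cell list, which includes Epx (-1.11 ± 0.26, adjusted p = 0.111) and Cpa3 (-0.74 ± 0.18, adjusted p = 0.119). Other members were Fcnb (-0.91 ± 0.32) and Ctsg (-0.58 ± 0.20) of granulocytes, Csf1r (-0.63 ± 0.18) and Ctss (-0.56 ± 0.15) of macrophages, Ebf1 (-0.64 ± 0.21) and Igll1 (-0.54 ± 0.14) of B cells, and Nkg7 (-1.02 ± 0.28) and Klrd1 (-0.62 ± 0.23) of cytotoxic lymphocytes. Megakaryocyte markers had a median of 0.04 (11 measured, 0 called by limma, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone, adjusted p = 0.719), with Itga2b at 0.24 ± 0.14 and Itgb3 at -0.28 ± 0.16. The macrophage call ended without WT 504 (median -0.15, adjusted p = 0.242), and without KO 551 its median was -0.21. The T and NK call ended without WT 497 (median -0.29, adjusted p = 0.271), WT 504 (-0.78, 0.056) or KO 548 (-0.35, 0.214), and with all mice under the block (0.166) and array weights (0.0674). Without WT 497 the neutrophil median was -0.22. On the same arrays the 3' minus 5' signal of the actin control probe sets was 1.65 to 1.67 (log2) in WT and 1.82 to 1.86 in KO, and that of Gapdh was 1.03 to 1.09 in WT and 1.0 to 1.05 in KO. Every list score was compared by an exact permutation test, whose smallest possible p in this design is 0.1, so none could pass.

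**Figure D3:**
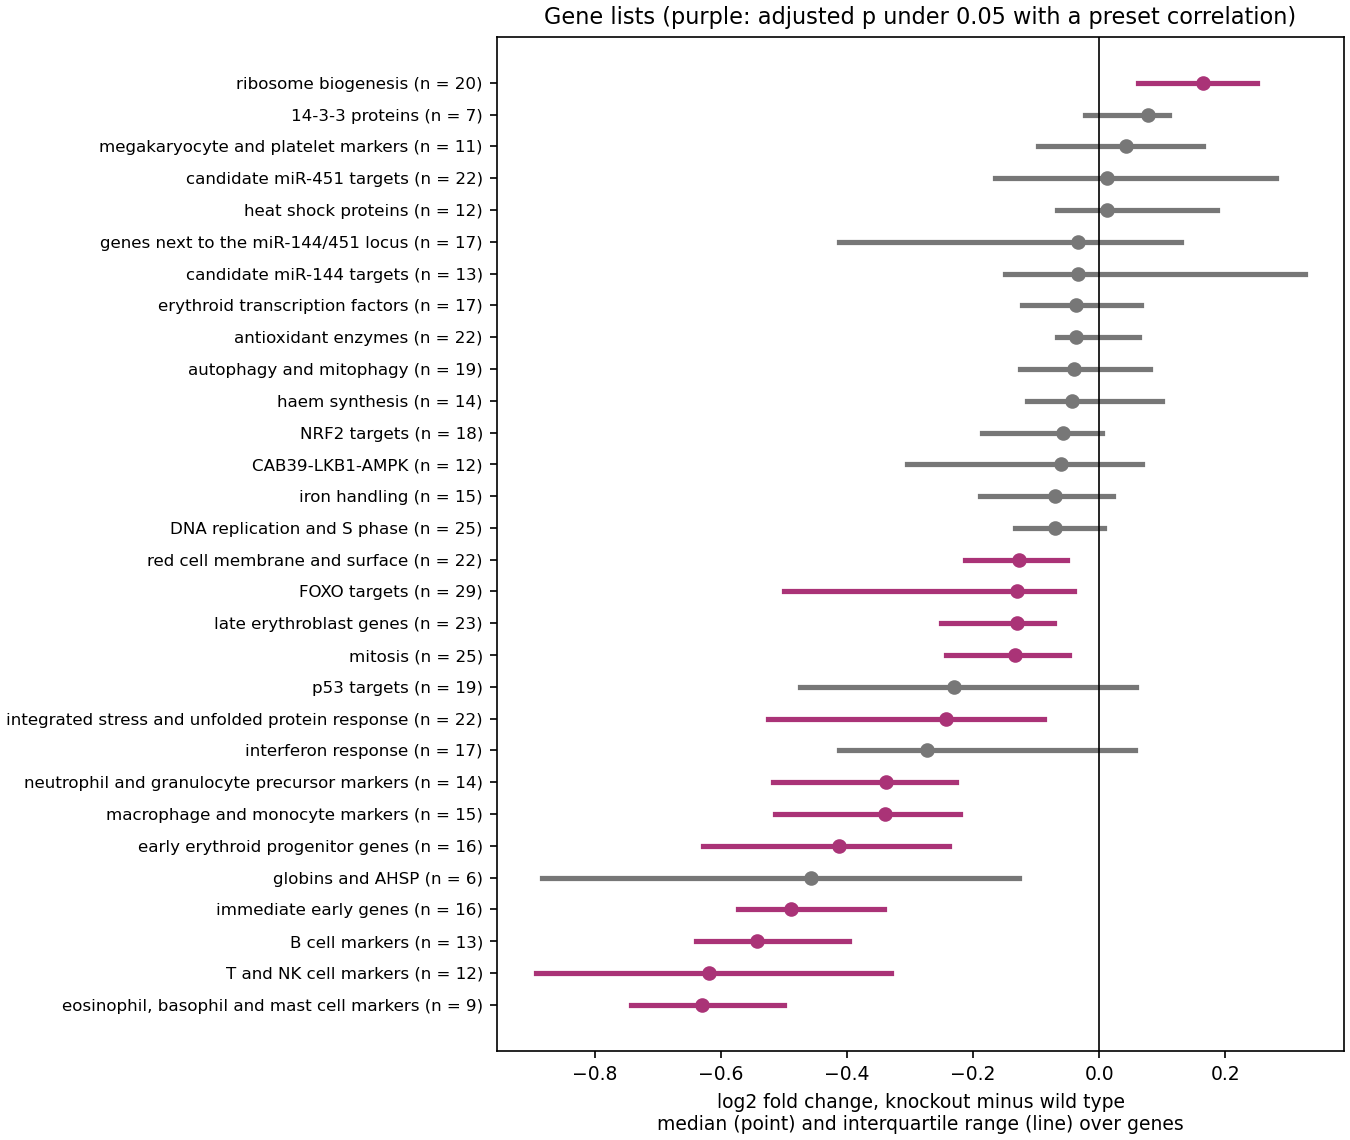
Median (point) and interquartile range (line) of the log2 fold change, knockout minus wild type, over the measured genes of each of the 30 lists, with n the number of genes; purple lists have an adjusted p under 0.05 with a preset correlation of 0.01. The 13 purple lists comprise 12 with medians from -0.63 to -0.13 and ribosome biogenesis at 0.17, and 0 remain called with an estimated correlation.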

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

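All alternatives here were planned, except the list tests without chromosome 11, chosen after seeing the data, which again called 13 lists. The 43 genes called higher and 27 lower became 275 and 197 with probe sets above the median level only, and 432 and 372 with an intensity trend and robust prior, which changes both settings at once; all 61 of the 70 genes that the filter kept, and all 70 with the trend, were called again. Quantile normalization gave 69 higher. A block for low against high label numbers, a guess at cohorts, gave 7 and 3, with 10 of the 70 called. An ordinary equal-variance test gave 3 and 4, a limit of 0.01 on the adjusted p 6 and 3, and a 2-fold minimum 26 higher. Without chromosome 11 there were 31 and 16. Leaving out 1 mouse, which leaves 5 arrays, gave 3 to 9 higher and 2 to 7 lower, and 5 to 12 of the 70 were called again. The 160 probe sets became 1010 (level filter), 1593 (trend), 17 (block) and 8 to 23 without 1 mouse. Called lists numbered 9 to 16, except 0 with an estimated correlation (0 at unadjusted p under 0.05) and 0 with the rotation test fry, which tests each list alone (13 at unadjusted p under 0.05, smallest adjusted p 0.0873). The 2 called genes near the locus became 10 (level filter), 8 (trend), 1 (quantile), 1 (cyclic loess), 1 (mean of probe sets), 0 (block) and 0 in every fit without 1 mouse; windows of 20 and 200 genes held 1 and 15. Xaf1 reversed to 0.485 as the mean of its probe sets, since its probe sets disagree; for the other changes the cause was not tested. Cyclic loess, array weights, the mean of probe sets, removal of probe sets ending in _x_at or _s_at, and adjustment over representative probe sets alone kept both gene counts within 1.5 times. Among the named genes, 41 single values newly passed the threshold under the settings with all mice, and 22 lost it with their sign kept. Most of these came with the trend and the block. Xaf1 also lost its call, with the reversed sign given above. Without 1 mouse 99 values no longer passed. No paired analysis was run, because litter, by which mice might be paired, was not used here. The planned seed-site test and its alternatives were not run. In simulated data with few changed probe sets, the fit without trend or filter called 0 of 67 changes of 0.5 on the log2 scale. That limit does not carry over to other fits of the same arrays. Cab39, at 0.467, was called with the level filter (limma adjusted p = 0.0318) and with the trend (0.00507).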

Other observations

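The tests of the strain stretch, of target release on chromosome 11, of dim signals, of megakaryocyte markers and of the brighter miR-451 candidates were chosen after the results they bear on had been seen. Of the 10 possible splits of the 6 mice into 3 and 3, the real one called 70 genes and 13 lists. The other 9 called at most 1 gene each, and 1 to 8 lists each. Every split thus called at least 1 list at the preset correlation. For genes and for lists, 1 split, the real one, gave as many as the real comparison. With 10 splits, a share under 0.05 cannot be reached. The other splits also mix the genotypes within each group. Any genotype difference therefore adds to their residual variance and lowers their counts of called genes. Correlations estimated in the 13 called lists ran from 0.08 to 0.631, above the preset 0.01, so the preset test was the more lenient.

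Among list members chosen after their values were seen, Prdx2 and Gpx4, which remove peroxides in red cells, were at -0.04 and -0.10. On chromosome 11, Igtp, next to Irgm2 and of the same family of interferon-inducible GTPases, was also called (1.33, adjusted p = 0.0229), while the interferon list was not called. In the limma fit without covariate or trend, no gene beyond the 190th measured gene on one side of the locus was called. That side held 745 measured genes in all, and uncalled changes beyond that point included Aoc3 at -1.77 and Wnk4 at 1.23. The trend fit called 105 genes of the chromosome, 44 of them within 200 genes of the locus on either side. The places of the others were not analysed here.

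Called genes gathered on chromosome 11, on both sides of the deleted locus. Release of direct microRNA targets does not account for the gathering as a whole, since 11 of the 23 called genes were lower. Called genes lay closer to the locus than random genes of the chromosome, at a mean distance of 215 genes against 364 (one-sided permutation p = 5e-04), which is what a stretch of another strain's chromosome, carried along from the targeted stem cells, may leave; strain sequence was not tested. Probe mismatches with no change of the transcript stay open: over 8 called genes, the other probe sets moved the same way by a median of 0.622 (bootstrap SE 0.46), within 2 standard errors of 0 as written beforehand for mismatches. Because this range also reaches the median called size of 1.25, it was read as undecided after the value was seen; 4 of the 13 other probe sets were called the same way (Slc2a4, Fam161a, Eral1 and Gdpd1) and 1 the opposite way (Xaf1). Of the 46 called genes placed on other chromosomes, 6 had a called neighbour within 20 genes, against a mean of 4.7 and a 95th percentile of 10 in random draws, so the data show no excess of such clusters there.

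Markers of other blood cells were lower in KO, with a mean difference of -0.488 over 5 lists. A general shift of dim signals is argued against by 5 of 5 list medians below the 2.5th percentile of level-matched lists, and WT 497 as sole source by a difference of -0.368 without it. The difference of the megakaryocyte markers lay 0.508 above that of the other lists (SE 0.17). It cannot decide on an equal drop of all other marrow cells. How much of each list's signal comes from such cells was not measured. Fewer stray myeloid and lymphoid cells in the KO sort, and lower expression of these genes within erythroblasts, both remain possible. The gate on Ter119 and CD71 selects against such cells, but the purity of the sort was not analysed here. The mean log2 level of the neutrophil list was 11.70 to 11.90 in WT and 11.16 to 11.53 in KO, above the array medians of 5.62 to 5.78. The difference in actin 3' signal between the genotypes leaves RNA quality open as well.

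As a whole, the candidate miR-451 list lay at percentile 58.4 of level-matched random lists. After values had been seen it was split by signal: the median of the 11 brighter candidates was 0.26, at percentile 99.89 of their own level-matched lists, and that of the 11 dimmer ones was -0.15. Ywhaz, Cab39, Vapa, Rab14 and Emsy were each at 0.33 or more, and Cpne3 at -0.52. Release from miR-451 therefore stays an open hypothesis here: a split chosen on the same values decides nothing, signals of different probe sets do not rank expression, and the list may include targets established in these mutants.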
